A study of Mus musculus with 4 samples.

How the data were processed

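RNA was sequenced from Flt3-negative LSK cells, the lineage-negative, Sca1-positive and cKit-positive bone marrow fraction that is enriched for hematopoietic stem cells. The mice were C57BL/6. Groups were taken from the sample titles: 2 control libraries and 2 libraries from mice lacking Tcf1 and Lef1. Total RNA was purified on Qiagen columns and libraries followed an Illumina protocol, per the labels' protocols.

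The authors deposited 1 table of FPKM, fragments scaled to transcript length and to the mapped fragments of the library, with 1 value per gene and library, per the file headers. Cufflinks, edgeR and SAMtools are named without versions, roles or order in the submitters' processing notes, together with the genome build mm9. The aligner, the annotation, any filter and the handling of reads that match several genes are not given in the sources used here. The table had 21677 gene entries with a symbol, a chromosome and a numeric gene ID, no symbol occurred more than once, and all 4 columns of values matched a sample title. No coordinates are given, since the annotation at hand was of another build than mm9.

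FPKM are not counts, so no count model was used. Absolute depth is unknown. Relative depth was estimated from low values, where the ratio of 2 libraries repeats when a gene has the same small number of fragments in both. The commonest ratio, rounded to 3 decimals, placed control library 2 at 1.12 times the reads of control library 1 (45 of 1270 low genes shared that ratio), deficient library 1 at 1.15 times (53 of 1332) and deficient library 2 at 1.36 times (105 of 1765). These estimates rest on small shares of the low genes. No interval for single values can be drawn from them.

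Genes with at least 1 FPKM in at least 2 libraries were tested, which left 10695. Values were analysed as log2(FPKM + 1), a scale that understates changes of low genes, with no further scaling. Differences between groups were tested with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes moderation with a trend, two-sided), and p-values were adjusted over all tested genes by the Benjamini-Hochberg method with a threshold of 0.05. An exact permutation test of 1 gene with 2 libraries against 2 cannot go below p = 0.333, so only the model that shares its spread across genes was used. The labels do not say whether the libraries of a group came from separate mice. The limma p-values thus rest on the spread between these libraries, pooled across genes, which may be technical.

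For the set tests, 33 gene lists were fixed from general knowledge of the tissue, and 847 of 856 listed members matched a symbol in the table. The 32 lists with at least 5 tested members were compared with all other genes by camera with a preset inter-gene correlation of 0.01, adjusted over the lists. At that preset, camera p-values take genes as nearly independent and measure the spread across genes, not between libraries. Camera with an estimated correlation and fry were run beside the preset form. With an estimated correlation, camera uses the few residual degrees of freedom of 4 libraries. A list can therefore fail that form without having correlated members. The lists, the tests, the rule for naming genes and most of the alternatives were set before the data were examined. By that rule the text names Tcf7 and Lef1, up to 12 of the largest rises and 12 of the largest falls that passed the test with both deficient libraries on the same side of both controls (unnamed gene models, microRNA and snoRNA genes left out), and in each list up to 4 passing members or, where none passed, the 2 members with the highest mean FPKM. Every gene named outside that rule, whether or not the text says so beside it, was named after its values were seen. Some genes that the rule selects are not reported here, in the text or the plots, but stay in the counts and set tests.

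The procedure was tested on 20 simulated data sets with 200 changed genes each, run on a median of 10452 genes in the same comparison. It recovered 11.9% of changes of 1 on the log2 scale, 76.8% of changes of 2 and 96.1% of changes of 3. Of its calls, 5.07% were unchanged genes. Changed genes were drawn from those with a mean log2 value above 2, and 30 other genes per data set were shifted by 0.5. Simulated genes varied independently, with the spread that the model had fitted and equal spread in both groups. A share of false calls near the threshold was thus built in, and these shares may not hold for the real libraries. Gene length and GC content for an added alternative came from GENCODE M21 transcripts matched by gene ID, which covered 96.8% of the tested genes. Other alternatives changed the pseudocount, the filter, the scaling, the moderation and the threshold, left out each library in turn, left out small RNA genes or sex-linked genes, or added a block for the number in the column names.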

Results

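Transcript levels were measured in 4 RNA-seq libraries of Flt3-negative LSK cells, a mouse bone marrow fraction that holds long-term and short-term hematopoietic stem cells. There were 2 control libraries and 2 libraries from mice in which Vav-Cre, a recombinase active across the blood lineages, had removed Tcf7 and Lef1. Tcf7 encodes Tcf1, and both Tcf1 and Lef1 are HMG-box transcription factors that partner beta-catenin in Wnt signalling. FPKM summed to 1135100 and 1086350 in the controls and to 1027570 and 1099040 in the deficient libraries. Values above 0 were listed for 14360 and 14103 genes in the controls, 14196 in deficient library 1 and 16173 in deficient library 2, while 10650, 10790, 10321 and 9756 genes reached 1 FPKM. Across genes, which are not independent replicates, log2 values correlated at r = 0.968 between the controls and 0.968 between the deficient libraries, at 0.960 to 0.962 between the controls and deficient library 1, and at 0.935 to 0.938 between the controls and deficient library 2.

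The targeted genes were examined first. Tcf7 (gene ID 21414, chromosome 11) had 7.17 and 5.22 FPKM in the controls and 0.608 and 0.142 in the deficient libraries, a mean of 6.20 ± 1.38 against 0.375 ± 0.329 (SD, n = 2). Its log2 change was -2.40 (SE 0.34), with a limma p of 0.000227 and a Benjamini-Hochberg adjusted p of 0.0578 over all genes, so it did not pass that test, although both deficient libraries lay below both controls. Lef1 (gene ID 16842, chromosome 3) stood at 0.0267 and 0 FPKM in the controls and at 0.267 and 0.00981 in the deficient libraries, too low in every library to be tested. A value per gene cannot show which exons the reads came from, so transcript left by a partly deleted allele is counted too.

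The groups also differed in sex-linked transcripts. Xist, the RNA that silences an X chromosome in female cells, had 9.69 and 10.8 FPKM in the controls and 0.0214 and 0.0183 in the deficient libraries (log2 change -3.46, SE 0.30, limma adjusted p = 0.00681). The Y-linked genes Eif2s3y, Ddx3y, Uty and Kdm5d rose by 6.34, 5.12, 3.75 and 2.49 on the log2 scale (adjusted p = 0.000371, 0.000827, 0.00532 and 0.0357). Ddx3y, for example, had 0.0212 and 0.0182 FPKM in the controls and 36.2 and 32.6 in the deficient libraries. Xist, Uty and Kdm5d did not pass without deficient library 2 (adjusted p = 0.0632, 0.0536 and 0.137). Sex and genotype coincide in these libraries and cannot be told apart, so the groups compared below differ in both.

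The main comparison asked which transcripts differ between Tcf1/Lef1-deficient and control cells. The MHC class II chain H2-Aa rose from 56.5 and 53.5 FPKM to 262 and 588 (log2 change 2.81, SE 0.35, limma adjusted p = 0.0415). Csrp3, a LIM-domain protein, rose from 11.3 and 9.52 to 40.2 and 38.6 (1.83, SE 0.24, adjusted p = 0.0454). The largest fall past the test outside the small RNA genes was that of Myl10, a myosin light chain, from 108 and 129 FPKM to 4.92 and 2.02 (-4.81, SE 0.35, adjusted p = 0.00309). Plscr2, of the phospholipid scramblase family, fell from 25.8 and 22.1 to 1.04 and 1.10 (-3.59, SE 0.30, adjusted p = 0.00543).

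Several chemokines fell. Cxcl12, which marrow stroma makes in large amounts, went from 17.2 and 16.7 FPKM to 2.61 and 1.81 (log2 change -2.49, SE 0.31, limma adjusted p = 0.0415). Other transcripts that stromal or endothelial cells can express, named after their values were seen, fell beside it without passing. Emcn fell by 3.14, Adipoq by 2.68, Vcam1 by 2.24, Ibsp by 1.89 and Lepr by 1.15 on the log2 scale. Vcam1 is counted in the macrophage list below. The values cannot show which cells Cxcl12 or these transcripts came from, and the sorted cells themselves may have made them. The inflammatory chemokines Ccl3, Ccl4 and Ccl5 fell by 2.12, 2.07 and 1.83 on the log2 scale (limma adjusted p = 0.0479, 0.0248 and 0.0357). Ccl4 went from 173 and 260 FPKM to 51.2 and 48.3. All of them lie on chromosome 11, as does Tcf7. Whether variants carried along with its targeted allele played a part was not tested for these genes. The C-type lectin Cd209f fell by 2.65 (adjusted p = 0.0357), from 7.59 and 5.89 FPKM to 0.289 and 0.172. Without deficient library 2, Csrp3, Cd209f, Cxcl12, Ccl3 and Ccl4 did not pass (adjusted p = 0.125, 0.128, 0.103, 0.115 and 0.0912), and without control library 2, Csrp3, Ccl3 and Ccl5 did not (0.0716, 0.0972 and 0.0546). H2-Aa did not pass at a pseudocount of 0.1 (adjusted p = 0.0506), at 5 FPKM or more (0.0618), after quantile normalization (0.0595), with moderation without a trend (0.136) or robust moderation (0.0513), or with Xist and Y-linked genes left out (0.0515). That last omission, chosen after the data were seen, also ended the calls of Cxcl12, Csrp3 and Ccl3 (0.0515, 0.0546 and 0.0575). Myl10, Plscr2, Eif2s3y and Ddx3y passed under every alternative in which they were tested except the absence of a low-value filter.

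**Figure D1:**
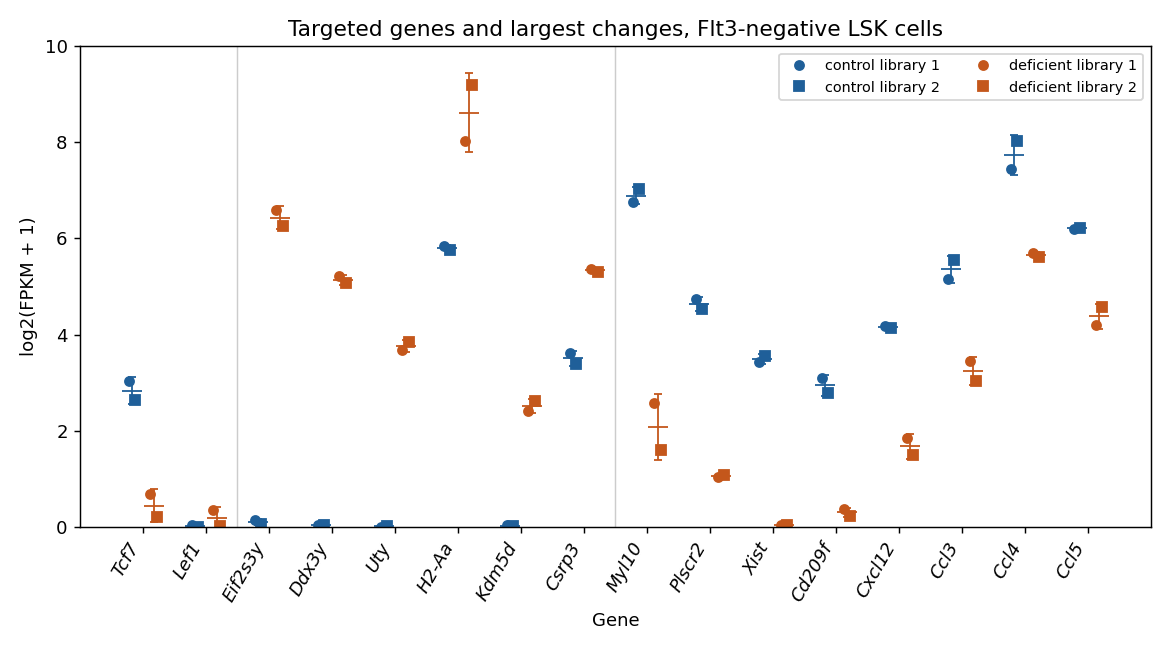
Values of the targeted genes and of the largest named changes in each library, as log2(FPKM + 1) on the vertical axis, with circles for library 1 and squares for library 2 of each group, controls in blue and deficient libraries in orange; the bar and whiskers give the mean and 1 SD (n = 2). H2-Aa stands at 56.5 and 53.5 FPKM in the controls and 262 and 588 in the deficient libraries, while Myl10 stands at 108 and 129 against 4.92 and 2.02.

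In all, 29 of 10695 genes passed the limma test, 8 higher and 21 lower in the deficient libraries. Of these, 13 were small RNA genes (1 higher, 12 lower), 5 were Xist or Y-linked, and 11 were others. Among the small RNA genes, named after their values were seen, Mir128-1 was listed at 108 and 96.8 FPKM in the controls and at 0 in both deficient libraries, and Snord38a at 418 and 374 and at 0. An exact 0 can be a failed estimate in this table: Ubb, a ubiquitin gene that every cell uses, was listed at 8765, 7696 and 7603 FPKM and at 0 in deficient library 2. With small RNA genes left out before adjusting, a choice made after the data were seen, 44 genes passed, 16 higher and 28 lower. Without deficient library 1 the count was 764, without control library 1 or 2 it was 105 or 47, and without deficient library 2 it was 21, of which 16 were among the 29. At an unadjusted p under 0.05 there were 574 higher and 1304 lower genes. Both deficient libraries lay above both controls for 2031 genes (19.0%) and below them for 3576 (33.4%), where chance gives 16.7% on each side. Together these were 52.4% of the genes tested, where chance gives 33.3%. Most of the excess lay on the lower side, in values that were not scaled further. The median log2 change of all genes was -0.11, and 0.05 after the libraries were centred on their medians.

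Antigen presentation genes rose as a group. The MHC class I list lay 0.90 above other genes on the log2 scale (camera adjusted p = 5.17e-11; adjusted p = 0.404 with an estimated correlation). None of its 15 tested members passed over all genes, 10 rose when adjusted over the list alone, and 13 were higher in both deficient libraries than in both controls. The peptide transporter Tap1, named after its values were seen, had 34.6 and 32.6 FPKM in the controls and 69.9 and 92.2 in the deficient libraries, and the immunoproteasome subunit Psmb8 had 415 and 356 against 610 and 720. By the fixed rule, B2m had 7352 and 6583 FPKM against 7789 and 6456, and H2-D1 had 921 and 1140 against 1351 and 1368.

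The list of MHC class II and dendritic cell genes lay 1.01 above other genes (camera adjusted p = 2.46e-05; adjusted p = 0.404 with an estimated correlation). Of its 12 tested members, H2-Aa alone passed over all genes, while 7 rose and 1, Flt3, fell when adjusted over the list alone. H2-Ab1, named after its values were seen, had 44.8 and 54.2 FPKM against 173 and 346. Irf8 and Tcf4, which dendritic cells also express, had 15.2 and 19.0 against 20.4 and 8.35 FPKM and 18.6 and 15.7 against 15.6 and 9.25. The type I interferon list did not pass (0.26 above other genes, camera adjusted p = 0.171). Its mean change was 0.10 and its median -0.02. Of its 35 tested members 1 passed over all genes, and 2 rose and 1 fell when adjusted over the list alone. That list passed without control library 1 (0.51, adjusted p = 0.000281) and without deficient library 1 (0.48, adjusted p = 0.0244), and lay near other genes without control library 2 (0.018, adjusted p = 0.953) or deficient library 2 (0.049, adjusted p = 0.876).

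Stem cell genes fell as a group. The list of stem cell identity and self-renewal lay -0.74 from other genes (camera adjusted p = 2.85e-06; adjusted p = 0.729 with an estimated correlation), with medians of -0.52 in deficient library 1 and -1.31 in deficient library 2 against the control mean. None of its 30 tested members passed over all genes, 10 fell when adjusted over the list alone, and 19 were lower in both deficient libraries. Cd34 had 323 and 384 FPKM in the controls and 210 and 99.95 in the deficient libraries, and Ifitm1 had 861 and 852 against 1131 and 460. Among members named after their values were seen, Hlf, a transcription factor of stem cells, had 29.3 and 31.2 against 12.6 and 2.67, and Procr, a stem cell surface receptor, 22.4 and 23.7 against 9.65 and 2.82. The gate markers Kit and Ly6a (Sca1) had 289 and 310 against 210 and 161 FPKM and 234 and 186 against 190 and 202.

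Related lists also fell, but they share members, so their falls are not separate evidence. Hoxa9 and Hoxb5 were also in the stem cell list. Egr1, Nr4a1 and Btg2 were in both the immediate early list and the quiescence list below, and Jun in the immediate early and Wnt lists. Of the 21 genes in the Hoxa and Hoxb list, only 5 were high enough to be tested. The Hoxa and Hoxb list lay -1.05 from other genes (camera adjusted p = 0.00187; adjusted p = 0.665 with an estimated correlation), none of its 5 tested members passed over all genes and all 5 fell when adjusted over the list alone, with Hoxa7 at 13.6 and 11.6 against 7.34 and 3.19 FPKM and Hoxa10 at 9.06 and 11.4 against 4.23 and 1.25. The immediate early list, genes switched on within minutes of a stimulus, lay -0.92 from other genes (camera adjusted p = 1.45e-07; adjusted p = 0.665 with an estimated correlation). Of its 19 members none passed over all genes and 13 fell when adjusted over the list alone. Rgs1 had 389 and 509 against 211 and 140 FPKM, Myc 167 and 244 against 278 and 185, and Fos, named after its values were seen, 290 and 311 against 127 and 70.1.

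The list of quiescence genes and cell cycle inhibitors lay -0.64 from other genes (camera adjusted p = 5.17e-05; adjusted p = 0.729 with an estimated correlation), with 0 of 19 members past the test over all genes and 6 lower when adjusted over the list alone. Txnip had 232 and 223 against 145 and 122 FPKM, and Cdkn2d 50.3 and 46.5 against 53.7 and 37.3. Wnt and beta-catenin target genes lay -0.78 from other genes (camera adjusted p = 0.00550, and 0.729 with an estimated correlation). Of 9 tested members 0 passed over all genes and 4 were lower when adjusted over the list alone: Tcf7 itself, Id2, Tcf7l2 and Jun. The list holds 25 genes. Axin2, Nkd1 and Nkd2 were among those too low to be tested, so the result does not cover them. Myc belongs to this list too, and Cd44 had 48.7 and 43.0 against 46.1 and 38.7 FPKM. Without Tcf7, the deleted gene, the remaining 8 members lay -0.60 from other genes (camera p = 0.0174 and 0.426 with an estimated correlation, unadjusted).

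Genes of the S, G2 and M phases rose as a group, 0.51 above other genes (camera adjusted p = 1.73e-10; adjusted p = 0.404 with an estimated correlation). None of the 42 members passed, over all genes or adjusted over the list alone, and 27 were higher and 1 lower in both deficient libraries than in both controls. Pcna had 455 and 397 against 438 and 451 FPKM, Rrm2 had 257 and 251 against 310 and 300, and Mki67, named after its values were seen, 19.99 and 23.1 against 22.6 and 18.3. DNA damage repair lay 0.36 above other genes (camera adjusted p = 0.000505; adjusted p = 0.665 with an estimated correlation), with 1 of 36 members, Rad54l, higher when adjusted over the list alone and none over all genes. Xrcc6 had 111 and 112 against 132 and 149 FPKM and Lig1 75.9 and 76.8 against 105 and 93.5.

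The unfolded protein and heat shock list lay 0.35 above other genes (camera adjusted p = 0.000462; adjusted p = 0.404 with an estimated correlation), with Hspd1 alone of 22 members higher when adjusted over the list alone and none over all genes. Hspa8 had 2584 and 2797 against 3637 and 4159 FPKM and Hsp90ab1 1502 and 1405 against 1754 and 1821. Oxidative phosphorylation lay 0.31 above other genes (camera adjusted p = 0.000693; adjusted p = 0.729 with an estimated correlation), with 0 of 42 members past the test over all genes or adjusted over the list alone, Cox4i1 at 2211 and 2106 against 1906 and 2672 FPKM and Ndufa4 at 2128 and 1972 against 1521 and 1567. It did not pass without deficient library 2 (0.09, adjusted p = 0.478) or after quantile normalization (0.12).

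Markers of other blood lineages moved in different directions. The erythroid list lay 0.91 above other genes (camera adjusted p = 1.45e-07; adjusted p = 0.665 with an estimated correlation), with medians of 0.15 in deficient library 1 and 1.42 in deficient library 2. None of its 23 members passed over all genes and 5 rose when adjusted over the list alone. Car1, a carbonic anhydrase of early erythroid cells, had 2309 and 2191 FPKM against 3301 and 8546, Car2 had 3850 and 4049 against 2773 and 6216, and the erythroid regulator Gata1, named after its values were seen, had 103 and 80.9 against 219 and 338. The granulocyte and monocyte list lay -0.60 from other genes (camera adjusted p = 6.55e-05; adjusted p = 0.729 with an estimated correlation), with 0 of 28 members past the test over all genes or adjusted over the list alone, and medians of -0.24 and -1.26 in deficient libraries 1 and 2. Elane had 4440 and 4729 against 3147 and 1373 FPKM, and Mpo 5014 and 4179 against 3907 and 1887.

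The macrophage list lay -0.85 from other genes (camera adjusted p = 0.000108; adjusted p = 0.665 with an estimated correlation), with 0 of 15 members past the test over all genes and 7 lower when adjusted over the list alone. Ctsd had 359 and 378 against 334 and 424 FPKM, Slc40a1 42.0 and 43.9 against 24.2 and 48.6, and Vcam1, named after its values were seen, 29.5 and 24.8 against 8.29 and 2.80. The stromal and endothelial list lay -0.89 from other genes (camera adjusted p = 0.0239; adjusted p = 0.729 with an estimated correlation). Cxcl12 was the only one of its 8 members to pass over all genes, and 4 fell when adjusted over the list alone: Cxcl12, Emcn, Ibsp and Lepr. The lymphoid priming list lay -0.62 from other genes (camera adjusted p = 0.0102, and 0.729 with an estimated correlation). Of its 20 members 0 passed over all genes and 7 were lower when adjusted over the list alone. Its median change was -0.26, with medians of -0.015 in deficient library 1 and -1.19 in deficient library 2 against the control mean. The log2 change of Igj, -5.19, weighed on the mean. Igj had 66.2 and 1153 FPKM in the controls and 13.9 and 2.89 in the deficient libraries, Il2rg 240 and 258 against 257 and 178, and Flt3, whose protein was absent by the sort, 37.8 and 45.9 against 14.2 and 6.54. This list did not pass without deficient library 2 (-0.24, adjusted p = 0.410).

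**Figure D2:**
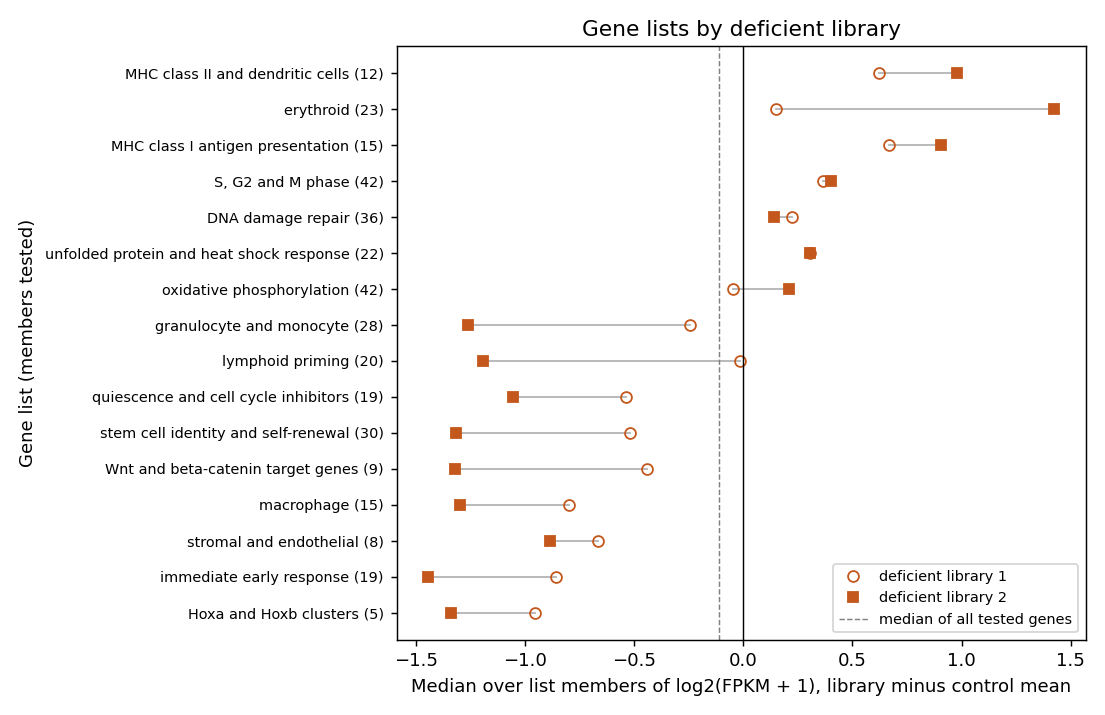
Median over each list's members of log2(FPKM + 1) minus the control mean, on the horizontal axis, for deficient library 1 (open circles) and deficient library 2 (filled squares), for the lists that passed camera with the preset correlation, sex-linked genes left out; the dashed line marks the median change of all genes, -0.11. The erythroid list stands at 0.15 and 1.42 and the stem cell list at -0.52 and -1.31 in the deficient libraries 1 and 2.

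In total 17 of 32 lists passed camera with the preset correlation, 8 higher (sex-linked genes among them, adjusted p = 0.000269, with 4 of 6 members higher and 1 lower over all genes, and 4 higher and 2 lower adjusted over the list alone) and 9 lower. With an estimated correlation none passed (smallest adjusted p = 0.404, with 2 lists at an unadjusted p under 0.05). With fry only the sex-linked genes did (4 lists at an unadjusted p under 0.05). The few degrees of freedom of 4 libraries limit the form with an estimated correlation. For the S, G2 and M phase genes that correlation was -0.014, under the preset 0.01, so correlated members do not account for their loss. The estimate was also low for the MHC class I (0.035) and class II (0.057) lists. Among others, it was far higher for the immediate early (0.64), stem cell (0.58), erythroid (0.55) and quiescence (0.54) lists. The granulocyte and monocyte and the Wnt lists both had 0.71. For lists with such high estimates, camera p-values at the preset correlation may be too small. The lists of adhesion and homing genes, TGF-beta response and Notch targets lay -0.33, -0.33 and -0.54 from other genes without passing (camera adjusted p = 0.0592, 0.0594 and 0.0594). Adhesion genes passed without control library 1, control library 2 or deficient library 1 (adjusted p = 0.0433, 0.0354 and 0.00746), TGF-beta response without deficient library 1 (-0.65, 0.0105) and Notch targets without control library 1 (-0.70, 0.0237), but without deficient library 2 these lists lay -0.13, -0.022 and -0.37 from other genes (adjusted p = 0.264, 0.529 and 0.222), and Notch targets lay -0.37 without control library 2 (0.257). Cholesterol synthesis lay 0.27 above (camera adjusted p = 0.0684), T and NK cell genes -0.42 (0.121), and mast cell, basophil and eosinophil genes -0.55 (0.214). Without deficient library 2 these last lists lay 0.28, -0.25 and -0.35 from other genes. The mast cell, basophil and eosinophil list lay -0.60 from them without control library 1. No member of the lists from adhesion to mast cell genes passed over all genes. Adjusted over the list alone, 1, 2, 3, 0 and 3 members were lower, in that order, while of the mast cell, basophil and eosinophil list 4 were higher and 9 lower. Among their members with the highest means, Klf10 had 129 and 124 against 80.8 and 68.6 FPKM, Dtx3 18.3 and 20.3 against 11.8 and 9.83, and Fcer1g 434 and 291 against 212 and 95.6, while Icam2 had 148 and 134 against 179 and 159 and Fdps 69.9 and 56.0 against 94.2 and 79.1. The values of Tgif1, Nkg7, Lat, Cpa3, Idi1 and Myc overlapped between the groups.

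The other lists had camera adjusted p-values of 0.487 (megakaryocyte and platelet), 0.542 (histones), 0.543 (Bcl2 family), 0.595 (B cell), 0.655 (p53 targets), 0.851 (cytosolic ribosomal proteins), 0.851 (glycolysis and hypoxia) and 0.988 (Polycomb and DNA methylation enzymes). No member of these lists passed over all genes. The B cell list had medians of 1.40 in deficient library 1 and -0.56 in deficient library 2, with Cd37 at 139 and 126 against 151 and 106 FPKM and Cd79b at 112 and 107 against 128 and 56.6. Without deficient library 2 it lay 1.21 above other genes (adjusted p = 9.89e-06), megakaryocyte genes 0.30 above (0.0260) and ribosomal proteins -0.15 from them (9.89e-06). Ribosomal proteins lay 0.32 above without deficient library 1 (0.00739) and histones 0.37 above without control library 2 (0.00657). The mean distance from other genes, the median change and the direction given by camera were not of the same sign for ribosomal proteins (0.08, -0.07 and lower), glycolysis (0.03, -0.28 and higher) and megakaryocyte genes (0.03, -0.12 and higher). For the histone, B cell and glycolysis lists camera gave higher and fry lower. Of the p53 targets, Bax had 27.7 and 31.7 against 49.9 and 84.5 FPKM and Sesn1 73.6 and 85.4 against 41.1 and 30.9, and 3 members were higher and 2 lower when adjusted over the list alone. Of the other members the rule selects in these lists, Ldha had 866 and 889 against 1147 and 1355 FPKM, Uhrf1 48.0 and 51.3 against 76.9 and 82.2 and Hist1h1b 146 and 144 against 177 and 284, and the rest overlapped between the groups.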

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

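Removal of the length and GC trend, omission of small RNA or sex-linked genes, the replicate block and the repeated choice of tested genes were added after the data were seen, and the cause of a change was not tested unless the setting itself gives it. The count of 29 genes (8 higher, 21 lower) became 2 with no filter on low values, where 17343 genes were tested, 17 at 5 FPKM or more, 58 after median centring, 52 with robust moderation, 44 without small RNA genes, 17 without Xist and Y-linked genes (which removes 5 of the calls) and 118 at an adjusted p under 0.1. Leaving out each library gave 21 to 764 genes with the tested genes kept, and 417, 317, 870 and 25 when they were chosen again on the 3 libraries left (without control 1, control 2, deficient 1 and deficient 2). The first rule was adopted after the second had been run. Here the lone library of a group is assumed to vary like the other group. After removal of the length and GC trend there were 38 genes, 19 higher and 19 lower. Under pseudocounts of 0.1 and 5, quantile normalization, TPM scaling, moderation without a trend and a minimum log2 change of 1 the count stayed within 1.5 times (20 to 32). The 2 genes with no filter were small RNA genes, so none of the named genes outside that class passed there. H2-Aa did not pass at a pseudocount of 0.1 (adjusted p = 0.0506), at 5 FPKM or more (0.0618), after quantile normalization (0.0595), with moderation without a trend (0.136) or robust (0.0513), or without Xist and Y-linked genes (0.0515), and its adjusted p ran from 0.00269 to 0.0139 when a library was left out. Calls also ended for Csrp3, Cxcl12 and Ccl3 without Xist and Y-linked genes, for Ccl3 at a pseudocount of 0.1, for Csrp3, Cxcl12, Cd209f, Ccl3 and Ccl5 at 5 FPKM or more, for these with Ccl4 and Kdm5d after TPM scaling, for Csrp3, Ccl3, Ccl4 and Ccl5 without a trend and for Cd209f, Ccl3 and Ccl5 after quantile normalization. Tcf7, at a log2 change of -2.40 above, passed after median centring (-2.23, adjusted p = 0.0345), robust moderation (-2.40, 0.0382), trend removal (-2.43, 0.0391) and omission of small RNA genes (-2.40, 0.0386). It was -3.91 at a pseudocount of 0.1 and -1.05 at 5, ran from -2.64 to -2.15 with a library left out (adjusted p = 0.0495, 0.0350, 0.0277 and 0.189 without control 1, control 2, deficient 1 and deficient 2), and had an adjusted p from 0.00815 to 0.355 over all alternatives. The number of lists past camera stayed between 15 and 21, but was 0 with the estimated correlation and 1 with fry. No list that passed turned its direction. With no filter the Hox and Wnt lists did not pass (-0.26 and -0.25). Lists that did not pass turned as follows: p53 targets 0.028 at a pseudocount of 0.1, 0.00092 after quantile normalization and -0.113 to 0.0196 with a library left out; Polycomb 0.011 at a pseudocount of 0.1, 0.025 after quantile normalization and -0.134 to 0.107 with a library left out; ribosomal proteins -0.035 after quantile normalization and -0.15 to 0.32 with a library left out (adjusted p = 9.89e-06 without deficient library 2); glycolysis -0.0089 with no filter, -0.026 after quantile normalization, -0.035 after trend removal and -0.0928 to 0.148 with a library left out; megakaryocyte genes -0.017 at a pseudocount of 5, -0.062 at 5 FPKM, -0.0027 after quantile normalization and -0.24 to 0.30 with a library left out; Bcl2 family 0.13 and mast cell genes 0.16 at 5 FPKM; B cell genes -0.38 to 1.21 and histones -0.16 to 0.37 with a library left out. The labels give no link between same-numbered libraries. Their deviations correlated at -0.05 across genes, which showed no common shift but cannot exclude a shared batch. With the numbers in the column names as a replicate block 245 genes passed, 52 higher and 193 lower. Tcf7 was then at -2.40 (limma adjusted p = 0.00815) and 18 lists passed camera. No symbol was repeated, so keeping the highest entry per symbol could not be run. Absolute depth is unknown, which limits low genes most.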

Other observations

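The tests of dilution, chromosome, dendritic cells and sex below were chosen after the results were seen, as was the list of interferon-inducible GTPases; those of small RNA genes, length and GC, and other splits were set before.

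The GTPases of the Irg and Gbp families, a list of 24 interferon-gamma-inducible genes chosen after the values were seen, had 23 tested members with a median log2 change of 0.89 and lay 1.24 above other genes, 0.747 without deficient library 2. Of them 17 were higher in both deficient libraries than in both controls and 0 lower, where chance gives 16.7% on each side. This is not independent evidence (camera p = 1.66e-13, and p = 0.208 with an estimated correlation). Iigp1 had 81.0 and 42.4 FPKM in the controls and 243 and 718 in the deficient libraries, and Igtp 98.1 and 76.5 against 289 and 709. The 33 type I interferon genes outside that list had a median of -0.11, that of all genes, with 9 higher and 12 lower, and lay 0.20 above other genes (camera p = 0.351, and p = 0.729 with an estimated correlation). Members moved both ways. Rsad2 had 9.39 and 9.21 FPKM against 3.19 and 2.81, and Ifit1 44.9 and 23.2 against 18.2 and 17.9. Zbp1 instead had 43.5 and 19.7 against 55.0 and 159, and Isg20 119 and 74.5 against 142 and 457. Gbp2 and Gbp3 of the type I list, higher in both deficient libraries than in both controls, were counted with the GTPases. The difference between the lists was not tested.

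Some transcripts stood out in single libraries. The pre-B-cell genes Igll1 and Vpreb1 had 180 and 50.8 FPKM in deficient library 1, against 17.1, 29.6 and 22.6 and against 4.91, 8.07 and 8.07 in control libraries 1 and 2 and deficient library 2. Igj, a plasma cell transcript, had 1153 FPKM in control library 2 and 66.2 in control library 1. Adipoq, an adipocyte hormone also made by marrow stroma, had 10.96 and 6.23 FPKM in the controls and 0.356 and 0.559 in the deficient libraries.

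The rise of MHC genes with these GTPases was weighed against 3 explanations. Tcf7 lies on chromosome 11 and Lef1 on chromosome 3, so neighbouring variants of another strain might travel with the targeted alleles. The 23 MHC genes, all on other chromosomes, had a median change 0.919 above that of all genes (bootstrap SE 0.146, taking genes as independent). Most lie on chromosome 17 and may move together, so that SE may be too small. Those elsewhere changed by 0.028 (B2m), 0.15 (Erap1), 0.62 (Nlrc5), 0.81 (Psmb10), 1.04 (Cd74) and 1.53 (Ciita) on the log2 scale. The rise on chromosomes other than 3 and 11 argues against variants within the MHC genes carried along with either targeted allele. It cannot address an effect on them through a gene on chromosome 3 or 11, which was not tested. For the GTPases carried-along variants stay open altogether. The 14 on chromosomes 3 and 11 had a median 1.21 above that of all genes (13 higher in both deficient libraries, 0 lower). The 9 elsewhere had a median 0.539 above (SE 0.507, 4 higher, 0 lower). Dendritic cells stay open too: of 10 of their other transcripts only 1 was higher in both deficient libraries, but 7 were under 1 FPKM in the controls (Zbtb46 had 0.467 and 0.965 FPKM against 0.331 and 2.06), and the control levels of Irf8, Tcf4 and Flt3 would hide a small share. Sex stays open with genotype: Ddx3y differed by 5.12 on the log2 scale, so sex and genotype cannot be told apart, and no other biological explanation was tested.

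The fall of stem cell, quiescence and immediate early genes with a rise of cell cycle and erythroid genes was weighed against length and GC content and against dilution. After removal of the gene length and GC trend, 5 of the 5 lists kept their direction and an adjusted camera p under 0.05 at the preset correlation. Dilution by mature cells of every type would be expected to raise the markers of each type. The granulocyte and monocyte list instead lay -0.603 from other genes while the erythroid list lay 0.91 above. Without deficient library 2 they still lay apart, at -0.144 and 0.27. This cannot decide on dilution, since the controls already held 5014 and 4179 FPKM of Mpo, a granulocyte and monocyte list member. Admixed erythroid cells alone would lower such transcripts too, so their admixture stays open. With an estimated correlation none of the lists in this paragraph passed camera (adjusted p = 0.404 to 0.729). A shift of the sorted population towards erythroid progenitors, by genotype, sex or sorting, may remain. By list median, deficient library 2 showed most of the erythroid rise (1.42, against 0.15 in deficient library 1). The medians of the S, G2 and M phase list were alike in deficient libraries 1 and 2 (0.37 and 0.40).

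Small RNA genes listed at 0 in both deficient libraries and at 1 FPKM or more in both controls numbered 11, and the highest number for another pair of libraries was 6. The bound set beforehand, 1.5 times the highest other pair, was passed. The excess over that pair is within counting spread (exact binomial p = 0.332), a requirement added after the value was seen. Taking the highest of the other pairs as reference makes a difference harder to see. The reverse pattern, both controls at 0 and both deficient libraries at 1 FPKM or more, held for 1 gene. Scarce reads on very short genes may still account for the excess. Of the 3 splits of the 4 libraries into 2 and 2, only 1, the genotype, gave as many as 29 genes; the highest other gave 4, and without small RNA genes the counts were 44 and 0. With 3 splits the share cannot fall under 0.05.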
